A study of Amphimedon queenslandica and Mnemiopsis leidyi and Nematostella vectensis with 36 samples.

How the data were processed

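The series holds 36 samples, of which 16 have a peak list analysed here. The others are 15 libraries of cytosine methylation, 3 of hydroxymethylation and 2 libraries with the empty HaloTag, and their data were not analysed here except for the 2 empty libraries, which enter through the authors' peak calls. Each construct and kind of DNA was a group of 1 library, taken from the sample titles.

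Per the labels' protocols, larval genomic DNA was sheared to a mean of 200 bp, given sequencing adapters, incubated with a HaloTag fusion made by in vitro translation and purified, and the recovered DNA was amplified for 20 cycles. For ampDAP-seq the adapter-ligated DNA was amplified for 11 cycles before the incubation. Per the submitters' processing notes, CASAVA 1.8.2, fastp, Bowtie2, BS-Seeker2, Bowtie and MACS2 were used in the series, and which aligner served these libraries is not given in the sources used here. Per the file headers, the authors called peaks with MACS2 2.1.2 for each library separately, from paired fragments, at a q cutoff of 0.05 and with at most 1 duplicate kept. The control was the empty HaloTag library of the same kind of DNA, the larger library of each pair was randomly down-sampled to the smaller, and an effective genome size of 166679601 bp was set. All 8 lists of a kind of DNA thus share 1 control library. The headers of both YY1 DAP lists carry another run letter than the other lists, with a meaning not given in the sources used here.

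Per the file headers, the pileup at a peak's summit is a signal of coverage, in fragments after down-sampling and not scaled to depth. Per the file headers, the authors' p-values and q-values are deposited as −log10 values per peak. Per the file headers, the fold enrichment is a ratio of a peak's pileup to the local background expected from the control. The deposited positions and lengths are in bp, counted from 1 on numbered contigs. Peaks with low fold enrichment and few fragments sit near the q cutoff, and down-sampling is random, so membership of weak peaks can change between runs of the caller. PCR after purification multiplies fragments, which the limit on duplicates reduces.

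Usable fragments ranged from 2161903 to 3168602 per library. Peak numbers were compared as log2(ampDAP/DAP) per construct, with an exact two-sided sign-flip permutation test over 8 constructs. Constructs of the same factor are not independent, and the 5 factors were the unit in an alternative. Peaks overlapped when they shared at least 1 bp. No list had overlapping or repeated peaks, so nothing was merged and counting subpeaks would change nothing. Chance overlap was measured by moving the other list by 5000 bp to either side and averaging. Shares carry 95% Wilson intervals for counting error. Lists were compared by the Jaccard index and an exact one-sided permutation of factor labels over 420 assignments. Correlations used permutation tests with 100000 resamples over 16 libraries and exact ones within the 8 of a kind of DNA.

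Regions were named by a rule fixed before the data were examined, as were the tests of peak numbers, Jaccard index and depth and the alternatives listed in the next paragraph. For each construct these were the 2 DAP peaks of highest −log10 q with an ampDAP partner, the highest DAP peak without one and the highest ampDAP peak without one, and in addition the regions with all 5 factors on both kinds of DNA. Some of the regions this rule picks are given by rank only.

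The alternatives were a −log10 q of at least 5, a fold enrichment of at least 5, lists without regions of at least 4 factors, reciprocal overlap of at least 50%, summits within 50 bp, lists of equal length, peak numbers per usable fragment, and leaving out single constructs. No reference genome was used here. The planned results on CpG content, motifs, octamers, promoters, gene lists and nearest genes, and the alternative restricted to long contigs, were therefore not run, and no region carries a gene annotation. The lists hold no gene identifiers, so a table of RefSeq gene names was not used here.

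The overlap code was tested on simulated lists with planted overlap. The recovered shares differed from the planted ones by at most 3.01 percentage points, which includes chance overlaps, and counts for 8 of 8 constructs equalled those of bedtools 2.31.1. In simulated draws without an effect, 5.5% passed 0.05 in the sign-flip test and 5% in the Jaccard test, and 100% of draws with a planted effect passed in both. The planted effects were large, with a mean of 2 SD in the sign-flip test, so the detection of smaller effects was not measured. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and matplotlib 3.10.9 for the plots.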

Results

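The binding experiments of the study measured where 5 transcription factors of the marine sponge Amphimedon queenslandica attach to fragments of the sponge's own genome in a test tube. In DAP-seq (DNA affinity purification sequencing), a factor made by in vitro translation and fused to the HaloTag, a protein tag that can be captured, was mixed with adapter-ligated genomic DNA, and the DNA it held was sequenced. In ampDAP-seq the same kind of DNA was first copied by PCR, here for 11 cycles, which removes cytosine methylation. The DNA came from swimming larvae at 0 h and had been sheared to a mean of 200 bp. The factors were NRF, YY1, EGR, GLI and SP41 (named SP in part of the labels). YY1, EGR, GLI and SP belong to families of zinc finger proteins, and GLI proteins act in Hedgehog signalling in other animals. NRF, YY1 and SP41 were tested as full length protein and as DNA binding domain (DBD), EGR and GLI as DBD. This gave 8 constructs, each with 1 library on native and 1 on amplified DNA, and thus 16 peak lists. A library with the empty HaloTag served as the control for each kind of DNA. The 18 methylation libraries of the series, from this sponge and other animals, were not analysed here.

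The 16 libraries held 2161903 to 3168602 usable fragments, against 2626764 in the DAP control and 2865511 in the ampDAP control. There were no replicate libraries, so no difference within a construct could be set against replicate error. Intervals given for single lists are 95% Wilson intervals, which cover counting error only. Positions are those of the deposited lists, on numbered contigs of an assembly whose build is not given in the sources used here. Fold enrichment and −log10 q of a peak are the authors' values and are used to describe, compare, rank or filter peaks within a list. Summaries of fold enrichment, such as numbers of peaks past a threshold, are also set side by side between lists. Such lists differ in control or in depth after down-sampling, so these summaries are not on a common scale.

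The first comparison asked whether factors found more or fewer sites once methylation had been removed from the DNA. The sponge factors went different ways. The NRF full length protein had 1439 peaks on amplified and 769 on native DNA, a ratio of 1.87, and the NRF DBD had 501 and 335. SP41 also had more peaks on amplified DNA, with 12006 against 7341 for the full length protein and 15399 against 11904 for the DBD. EGR had 6336 peaks on amplified and 12855 on native DNA, and GLI had 4837 and 8828. YY1 was split by construct, since the full length protein had 1606 peaks on amplified against 4528 on native DNA, whereas its DBD had 18619 against 13140.

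On the log2 scale the ampDAP to DAP ratios ran from −1.50 for YY1 full length to 0.90 for NRF full length, with 5 constructs above 0 and 3 below. Their mean was −0.04 ± 0.93 (SD, n = 8), which did not differ from 0 in an exact two-sided sign-flip permutation test (p = 0.906, where 0.00781 was the smallest p possible). The sign of the mean depended on single constructs: it was 0.17 without YY1 full length, 0.10 without EGR and 0.08 without GLI. Restricting the lists to peaks of at least 5-fold enrichment gave log2 ratios of 1.71 for NRF full length, 1.64 for YY1 DBD, 1.75 for SP41 full length and 1.04 for SP41 DBD, and of −0.17 for NRF DBD.

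**Figure D1:**
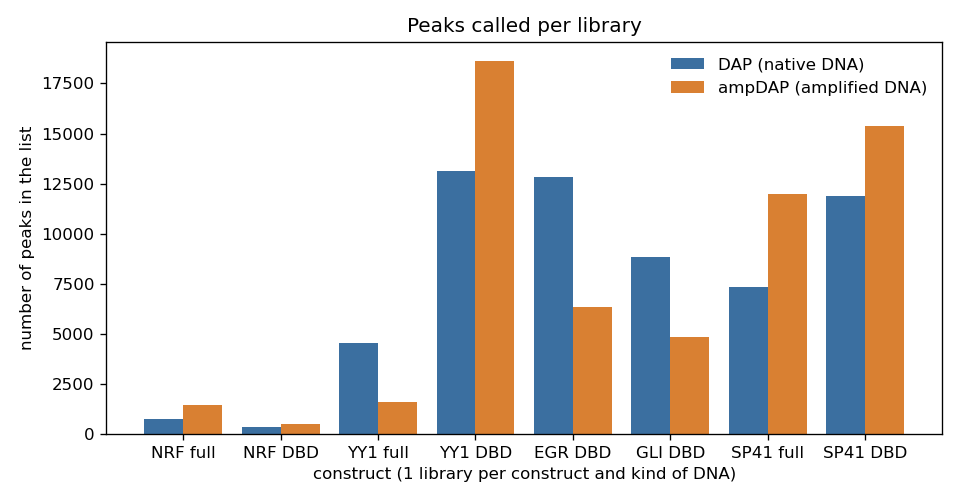
Number of peaks (vertical axis, from 0) in each of the 16 lists, with 1 bar per library, for DAP on native DNA and ampDAP on amplified DNA of each construct. YY1 full length, EGR and GLI had fewer peaks on amplified DNA, and the other constructs had more, up to 18619 for YY1 DBD.

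The second comparison asked whether a construct bound the same regions on native and amplified DNA. Most regions of SP41 full length and YY1 DBD found on native DNA were found again on amplified DNA, 77.4% (76.4 to 78.3) and 70.0% (69.2 to 70.8) of the DAP peaks. SP41 DBD followed with 61.2%, NRF DBD with 52.8% and NRF full length with 49.9% (46.4 to 53.5). EGR had 41.8%, YY1 full length 26.6% and GLI 25.4% (24.5 to 26.4). In the other direction 86.1% of the EGR ampDAP peaks and 75.2% of those of YY1 full length lay in a DAP peak, against 26.7% (24.5 to 29.0) for NRF full length and 35.3% for NRF DBD. The SP41 lists, YY1 DBD and GLI lay between 46.6 and 49.3%. The order of the constructs and the gap between the directions depended on the lengths of the lists. With lists of equal length, EGR was highest among DAP peaks with 65.0%, before SP41 full length with 62.0% and YY1 DBD with 57.25%. GLI stayed lowest there, with 32.1%. Among ampDAP peaks EGR then had 66.3% and YY1 full length 54.4%.

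The strongest shared regions were often held by several factors. For both NRF constructs, the 2 highest ranked DAP peaks with an ampDAP partner were at contig 13273, positions 8426 to 8754 for the full length protein, and contig 13405, positions 87125 to 87445. The first also held peaks of GLI, SP41 and YY1, and the second of GLI and SP41. For YY1 full length they were at contig 3679, positions 90 to 345, with EGR and SP41, and contig 13520, positions 6113 to 6470, with EGR and GLI. Those of YY1 DBD lay side by side on contig 11028, at positions 144 to 1169 and 1336 to 2795, and held no peak of another factor. For EGR they were at contig 13196, positions 87428 to 87908, with GLI, SP41 and YY1, and contig 8294, positions 220 to 485, with GLI, NRF and SP41. GLI had contig 9367, positions 28 to 484, with EGR and SP41, and contig 12882, positions 27907 to 28251, with NRF and YY1. Both SP41 constructs had their strongest shared peak at contig 12932, positions 1462 to 1746 for the full length protein, where all 5 factors had a peak on at least 1 kind of DNA.

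Over the 8 constructs, a mean of 50.7% ± 18.9 (SD) of the DAP peaks overlapped an ampDAP peak by at least 1 bp, and 51.8% ± 19.6 of the ampDAP peaks overlapped a DAP peak. With the other list moved by 5000 bp the means were 4.03% and 3.79%. Sharing went with strength within every list: between the weakest and the strongest quartile by −log10 q it went from 4.17 to 99.0% for NRF full length DAP peaks, from 12.3 to 82.3% for EGR DAP peaks and from 15.1 to 40.7% for GLI DAP peaks. Shares of single constructs moved with the thresholds and list lengths. Lists of equal length gave 54.2% for YY1 full length and 65.0% for EGR DAP peaks and 44.7% for NRF full length ampDAP peaks. The thresholds were applied to both lists, so a partner had to pass them too. At 5-fold or more, the shares among DAP peaks were 92.7% for NRF full length, 8.35% for GLI and 26.1% for SP41 DBD. Among ampDAP peaks they were 54.9% for NRF DBD, 21.5% for YY1 DBD, 14.2% for GLI, 19.9% for SP41 full length and 12.7% for SP41 DBD. In the whole ampDAP list, 206 of the 500 GLI DAP peaks of highest fold enrichment had a partner. A −log10 q of at least 5 gave 81.0% for NRF full length DAP peaks.

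**Figure D2:**
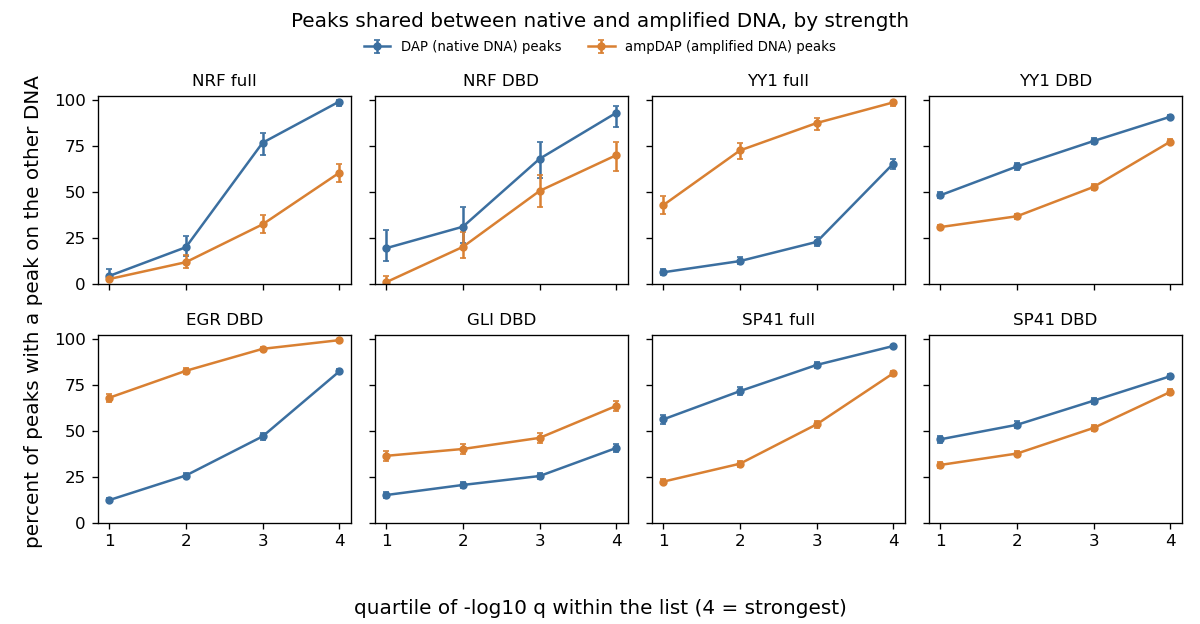
Percent of peaks with a peak of the same construct on the other DNA (vertical axis), by quartile of −log10 q within the list (horizontal axis, 4 is the strongest), for DAP and ampDAP peaks of each construct, with 95% Wilson intervals. In each panel the share is higher in quartile 4 than in quartile 1, and NRF full length DAP peaks reach 99.0% where its ampDAP peaks reach 60.3%.

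The third comparison took the strongest peaks of each list by −log10 q and asked which had no partner on the other DNA. At this fixed number, such peaks were most frequent in the NRF ampDAP lists and both GLI lists. Of the strongest 100 NRF full length ampDAP peaks, 26 (18.4 to 35.4%) had no DAP peak, whereas 0 of its strongest 100 DAP peaks lacked an ampDAP peak, which allows up to 3.70%. The NRF DBD had 30 such ampDAP and 11 such DAP peaks. GLI had them on both sides, with 26 of the strongest 100 ampDAP peaks and 38 (29.1 to 47.8%) of the strongest 100 DAP peaks without a partner. In YY1, EGR and SP41 the numbers were 0 to 8. The partner lists differed in length, with 769 DAP and 1439 ampDAP peaks for NRF full length, so a DAP peak had more peaks to meet. With whole lists cut to equal length, 44.7% of NRF full length peaks had a partner in either direction. The 100 peaks are a larger part of the short NRF lists than of the others, and in the strongest quartile the shares with a partner were 60.3% for NRF full length and 69.8% for NRF DBD ampDAP peaks and 40.7% for GLI DAP peaks, against 65.3% for YY1 full length DAP and 71.1% for SP41 DBD ampDAP peaks.

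The strongest NRF full length ampDAP peak without a DAP peak was at contig 13373, positions 64453 to 64803, with 111-fold enrichment and rank 2 among its 1439 peaks, and no other factor had a peak there. That of NRF DBD was at contig 13331, positions 30879 to 31180, with rank 4 of 501, in a region that also held an EGR peak. On the other side, the strongest NRF full length DAP peak without an ampDAP peak had rank 136, at contig 13520, positions 615882 to 616120, and that of NRF DBD had rank 32, at contig 13375, positions 113564 to 113817. For GLI the DAP peak at contig 5896, positions 272 to 457, had rank 9 and lay in a region with an EGR peak. The GLI ampDAP peak at contig 12686, positions 12659 to 12806, had rank 11. The SP41 DBD ampDAP peak without a DAP peak of highest rank, 7, was in the same place, at positions 12660 to 12810. The SP41 full length ampDAP peak at contig 13490, positions 218233 to 218483, had rank 22 and lay in a region with EGR and YY1. The highest ranks of DAP peaks without an ampDAP peak were 28 for SP41 DBD, 61 for YY1 DBD, 92 for YY1 full length, 137 for SP41 full length and 192 for EGR. Those of ampDAP peaks without a DAP peak were 136 for YY1 DBD, 196 for YY1 full length and 474 for EGR. Ranking by fold enrichment, an alternative chosen after seeing the data, gave 38 for NRF full length and 36 for NRF DBD on amplified DNA and 59 for GLI on native DNA. It also gave 35 for GLI, 9 for YY1 DBD, 13 for SP41 full length and 28 for SP41 DBD among ampDAP peaks, and 14 for SP41 DBD, 3 for YY1 DBD and 2 for YY1 full length among DAP peaks.

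**Figure D3:**
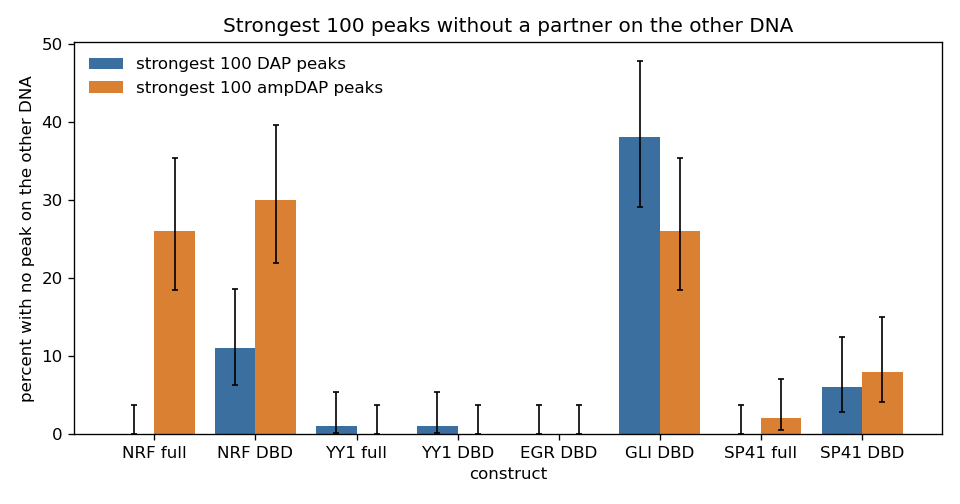
Percent of the strongest 100 peaks by −log10 q with no peak of the same construct on the other DNA (vertical axis, from 0), for DAP and ampDAP lists of each construct, with 95% Wilson intervals. NRF full length has 26 on amplified DNA and 0 on native DNA, and GLI has 26 and 38.

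The fourth comparison asked how the isolated DBD compared with the full length protein. In the lists as deposited, NRF had more peaks as full length protein, and YY1 and SP41 had more as DBD. The NRF DBD list was nearly contained in the full length list on native DNA, where 90.8% (87.2 to 93.4) of DBD peaks and 39.5% of full length peaks were shared. On amplified DNA these shares were 66.5% and 23.1%. For YY1 the full length list lay mostly within that of the DBD, with 69.3% of full length peaks shared on native and 86.9% (85.1 to 88.4) on amplified DNA, where the DBD had 11.6 times as many peaks. For SP41, 69.1% of full length peaks were shared on native and 64.1% on amplified DNA, and the DBD had 1.62 and 1.28 times as many peaks. Among peaks of at least 5-fold enrichment the order was turned for SP41, with 6219 full length against 3748 DBD peaks on amplified and 1851 against 1818 on native DNA, and NRF had 303 against 287 on native DNA.

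The mean share of full length peaks in a DBD peak was 58.7% ± 23.1 (SD over 3 factors on both kinds of DNA, n = 6), against 4.98% with the DBD list moved by 5000 bp. No test was planned or made; the sign-flip test used for peak numbers cannot give a p below 0.25 with 3 factors, and other tests were left out. Lists on the same kind of DNA were called against the same control library, and with the DBD list of the other DNA, which shares no control, the mean was 51.4% ± 23.7.

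The fifth comparison asked whether lists grouped by factor. Leaving aside the lists of the same construct, every list of NRF, YY1 and SP41 had its highest Jaccard index with a list of the other construct of its factor, and EGR and SP41 also overlapped each other. The Jaccard index, base pairs shared by a pair of lists over base pairs in either, was 0.377 between the NRF constructs and 0.321 between the SP41 constructs on native DNA, and 0.178 between the YY1 constructs. EGR reached 0.254 with SP41 DBD and 0.226 with SP41 full length on native DNA, and 0.190 with SP41 full length on amplified DNA. GLI was closest to EGR on native DNA, with 0.0980, and to SP41 DBD on amplified DNA, with 0.0672. NRF had at most 0.0281 with any list of another factor, reached with YY1 full length on amplified DNA. The index of the short NRF lists with long lists is held low by the difference in length. By share, 26.55% of NRF full length ampDAP peaks lay in a YY1 DBD ampDAP peak, against 5.73% with that list moved by 5000 bp. Only 23.1% lay in an NRF DBD ampDAP peak. Of the NRF DBD DAP peaks, 31.9% lay in an SP41 full length ampDAP peak, but 90.8% in an NRF full length DAP peak.

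Pairs of constructs of the same factor had a mean index of 0.25 and pairs of different factors 0.0399. The difference of 0.210 was the highest of the 420 ways to assign the constructs to factors (exact one-sided permutation test, p = 0.00238, the smallest possible). It was 0.249 on native DNA (p = 0.00238, exact permutation test) and 0.172 on amplified DNA (p = 0.00476, exact permutation test). On amplified DNA the YY1 constructs had an index of 0.0617, below the 0.0620 of EGR with GLI. The assignment by factor was therefore not the highest there. The YY1 index is held low by length, since the full length list covered 311531 bp and the DBD list 4157449 bp. By share, 86.9% of the YY1 full length ampDAP peaks lay in a DBD ampDAP peak. Of the GLI ampDAP peaks, 17.1% lay in an EGR ampDAP peak. Part of the overlap of lists on the same DNA may come from the shared control. Between DAP lists and ampDAP lists, which share none, the means were 0.195 and 0.0343 (p = 0.00238, exact permutation test), in an alternative chosen after seeing the data.

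**Figure D4:**
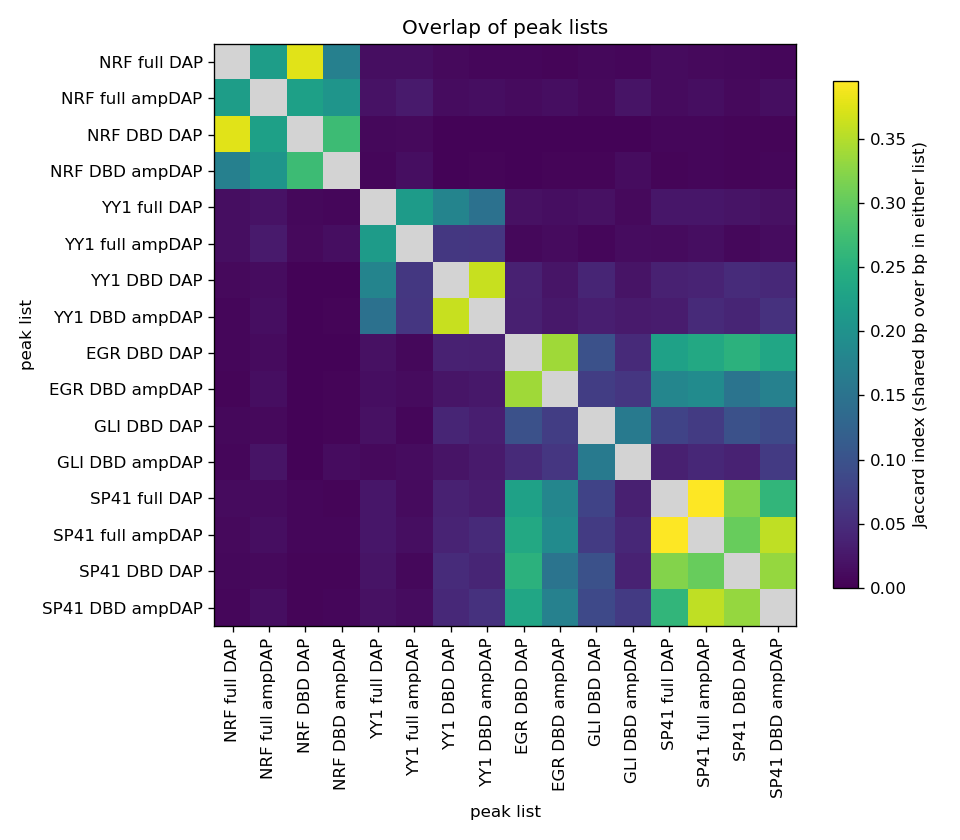
Jaccard index of every pair of the 16 peak lists (colour scale from 0, grey on the diagonal), with lists named by construct and kind of DNA on both axes. DAP lists of EGR and SP41 DBD reach 0.254, whereas the YY1 full length ampDAP list reaches 0.0638 and 0.0617 with the YY1 DBD lists, below the 0.0980 of GLI with EGR on native DNA. The index of this short YY1 list with the long DBD lists is held low by the difference in length.

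The 120443 peaks merged into 52356 regions. Peaks of 1 factor only made up 36631 regions (70.0%), 11083 regions held 2 factors, 3851 held 3, 742 held 4 and 49 held all 5. A single region had peaks of all 5 factors on each kind of DNA, at contig 13516, positions 142624 to 143444. It was in 15 of the 16 lists.

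The number of peaks did not follow depth in a detectable way. Over the 16 libraries, Pearson's r between usable fragments and peaks was −0.361 (permutation p = 0.168) and Spearman's rho was −0.215 (permutation p = 0.424). Within the 8 DAP libraries r was −0.577 (exact permutation p = 0.132) and rho −0.524 (exact permutation p = 0.197). Within the 8 ampDAP libraries r was −0.210 (exact permutation p = 0.611) and rho −0.0476 (exact permutation p = 0.935). Without EGR DAP and NRF full length DAP, the libraries farthest from the median depth, r was −0.139. All Benjamini-Hochberg adjusted values over the 10 tests of this family were at least 0.655.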

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

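In this part, the tests of depth and of library yield and the Fisher's exact tests were chosen only after the results were seen. Measures over the 8 constructs were searched for a construct far from the rest by Dixon's test, which flags about 5% of groups by chance.

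YY1 full length, EGR and GLI had log2 ampDAP to DAP ratios of peak numbers of −1.50, −1.02 and −0.87, opposite in sign to the ratios of NRF full length, NRF DBD, YY1 DBD, SP41 full length and SP41 DBD. With 1 library each, the difference was not tested.

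The YY1 constructs differed in direction, as did those of NRF among peaks of at least 5-fold enrichment, with 1.71 for the full length protein and −0.17 for the DBD. Library depth is argued against, since the full length ampDAP library was the deeper one, with 2842290 against 2449481 usable fragments, a log2 ratio of 0.21. A lower yield of the full length ampDAP library cannot be told apart from other causes: 68.8% of the full length DAP peaks without an ampDAP partner lay in a YY1 DBD peak on amplified DNA, against 5.61% with that list moved by 5000 bp, but also against 1145 of the 1205 shared full length DAP peaks, and 65.0% of those without a partner lay in a DBD peak on native DNA. The DBD lists cannot decide this, since the DBD could hold these sites whatever the yield of the full length library. Of the full length peaks, 51.4% on amplified and 45.8% on native DNA were of at least 5-fold enrichment. In numbers these were 825 and 2075 peaks. The shares cannot decide on the yield, since a library of lower yield would lose weak peaks below the q cutoff. A dependence of the full length protein itself on native DNA remains open and untested. Both YY1 DAP lists carry another run letter, of unknown meaning, than the YY1 ampDAP lists. For YY1, whatever it stands for thus cannot be told apart from the kind of DNA. The letter was the same for both constructs on native DNA, though their peak numbers moved in opposite directions.

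GLI stood far from the other constructs in the strongest 100 DAP peaks without an ampDAP peak, with 38. Ranking by q is argued against as the cause, since 59 of the 100 peaks of highest fold enrichment had no partner either. Regions that other zinc finger constructs bind on native DNA cannot be told apart from other causes: of the 38 peaks, 71.1% (55.2 to 83.0) lay in an EGR or SP41 DAP peak, against 48.4% (36.4 to 60.6) of the GLI peaks with a partner and 13.2% with the lists moved (Fisher's exact test, two-sided, p = 0.0371). The shares were 75.3 and 50.4% for the strongest 200 by −log10 q (Fisher's exact test, p = 0.000419) and 62.2 and 50.8% for the strongest 500 (Fisher's exact test, p = 0.0116), but 62.7 and 53.7% for the 100 peaks of highest fold enrichment (Fisher's exact test, p = 0.412), and 40.2 and 42.5% over all GLI DAP peaks (Fisher's exact test, p = 0.0588), so the excess depended on ranking and number. The pattern was not confined to native DNA, since 26 of the strongest 100 GLI ampDAP peaks had no DAP peak. Of the GLI peaks, 14.1% on native and 15.2% on amplified DNA were of at least 5-fold enrichment. The highest fold enrichment in these lists was 10.78 and 10.85. SP41 DBD DAP peaks had a similar share of 15.3%, but only 6 of their strongest 100 had no partner. Whether weak enrichment left GLI partners uncalled was not tested. A preference of GLI itself for native DNA was not tested either and stays open.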

How the results depend on the processing

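The alternatives by covered base pairs, without the YY1 constructs, with lists that share no control, with fragments after down-sampling and with ranking by fold enrichment were chosen only after the data were seen. The mean log2 ratio of peak numbers did not differ from 0 under any alternative, with exact permutation p from 0.477 to 0.945. Its sign reversed to 0.13 with a −log10 q of at least 5, to 0.34 with at least 5-fold enrichment and to 0.11 without the YY1 constructs, and leaving out single constructs gave −0.17 to 0.17, because values of either sign nearly cancel. The ratio of NRF DBD reversed to −0.17 with at least 5-fold enrichment, and the cause was not tested. The other ratios of single constructs kept their sign under all alternatives run. The mean shares of DAP, ampDAP and full length peaks with a partner stayed within 1 SD of the main values under all alternatives run, between 43.3 and 57.3%, 38.5 and 55.4%, and 48.8 and 72.3%. These SDs, of 18.9, 19.6 and 23.1 points, are spreads between constructs and thus a wide margin. With both lists cut to 5-fold enrichment or more, the shares of 7 constructs left their Wilson intervals among DAP peaks, and of 7 among ampDAP peaks. The difference in Jaccard index kept its direction and p = 0.00238 (exact permutation test) under all alternatives run, between 0.160 and 0.311. For amplified DNA alone it was 0.172, with p = 0.00476 (exact permutation test). Correlations with depth kept their sign and did not pass 0.05. The stricter thresholds kept 14.1 to 85.7% of a list's peaks by fold enrichment and 57.4 to 95.2% by −log10 q. The alternative restricted to long contigs and those of the CpG, motif and promoter results were not run, because no genome was used here. With 1 library of 2161903 to 3168602 usable fragments per list, an absent peak means only that none was called at this depth.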

Other observations

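The comparisons between factors in this part, and the tests of weaker enrichment and of unrecovered DNA, were chosen only after the data were seen. EGR and SP41, from zinc finger families known in other animals to bind GC-rich sites, shared many regions whichever DNA was used. Of the EGR DAP peaks, 42.9% lay in a DAP peak of SP41 DBD and 46.5% in an ampDAP peak of SP41 DBD, which has no control library in common, against 7.24% and 7.85% with those lists moved by 5000 bp. Of the EGR ampDAP peaks, 57.7% lay in an ampDAP and 45.2% in a DAP peak of SP41 DBD. For GLI DAP peaks the shares in DAP peaks of EGR and SP41 DBD were 28.4% and 27.5%.

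Strong NRF sites on amplified DNA without a native counterpart were followed up. Weaker enrichment of the DAP libraries is open: the 26 full length ampDAP peaks without a DAP peak among the strongest 100 had a median −log10 q of 303.6 against 323 for the other 74 (permutation p = 0.589) and a median fold enrichment of 38.4 against 31.8 (permutation p = 0.160), and for the 30 and 70 of the DBD these were 48.2 against 54.9 (permutation p = 0.406) and 11.8 against 10.1 (permutation p = 0.0527), with a lower median pileup of 69 against 93 (permutation p = 0.0389). These values describe ampDAP peaks and do not measure the DAP libraries. In the whole lists of the full length protein, 303 DAP and 992 ampDAP peaks were of at least 5-fold enrichment. For the DBD the numbers were 287 and 255, which does not show a weaker DAP library for that construct. Peaks with a partner had a median fold enrichment of 7.23 on native and 13.25 on amplified DNA for the full length protein. For the DBD these medians were 10.51 and 7.34. Lower values on native DNA can come from a weaker library or from weaker binding, so they cannot decide between these. DNA missing from the DAP libraries is argued against for part of the 26 sites, since 11 (42.3%, against 11.5% with lists moved) lay in a DAP peak of another factor. Some of the 11 may overlap by chance, and 1 bp was enough, so it is not excluded for any single site. It cannot be told apart for the other 15. On amplification bias, 53.8% (35.5 to 71.2) of the 26 lay in an ampDAP peak of another factor, against 83.8% of the sites with a DAP peak. The share set beforehand as the mark of such a bias lies inside this interval, so the test cannot decide. The contrast with the other 74 sites cannot decide either, since 73.0% of those also lay in a DAP peak of another factor. A bias common to the amplified DNA would also be in the control, against which these peaks had a median fold enrichment of 38.4. A bias of the single NRF library remains open. A difference between native and amplified DNA at these sites cannot be told apart from these causes either: all 26 sites (100%) lay in ampDAP peaks and 2 (7.69%) in DAP peaks of the NRF DBD, but 90.8% of that DAP list lay in full length DAP peaks, so the DAP lists of the NRF constructs are not independent. Loss of methylation may be that difference, as a hypothesis, and the methylation data that could test it were not analysed here.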
